A study of Homo sapiens with 5 samples.

How the data were processed

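RNA sequencing was done on 5 libraries of total RNA from 2 established human cell lines of esophageal squamous cell carcinoma. KYSE30 gave 1 control library and 1 library with GPRC5A overexpression. KYSE520 gave 1 library with a control short hairpin RNA (shControl) and 2 libraries with a hairpin RNA against GPRC5A, which the labels number 1 and 2. The labels do not say whether these numbers stand for different hairpins or for repeated cultures, and both libraries were taken as 1 knockdown group.

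For each library the authors deposited a table of raw counts per gene, as whole numbers with no normalization, and a table of FPKM (fragments scaled to gene length and library total) for the same genes. Per the labels, reads were processed with HISAT2 and HTSeq, for which no version was given, and R 3.2.0. The labels name a mouse genome build, while 96.7% of the Entrez identifiers and 94.4% of the symbols in the tables were found in a human RefSeq gene table. The build and annotation version behind the counts are therefore open, and no coordinates are given. The strand setting and the handling of reads shared between paralogs were not stated, so counts of genes in close families (PSG, CGB, HLA, keratin, IFITM, AKR1C and histone genes) and of genes overlapping on opposite strands are uncertain. All 98909 deposited FPKM values above 0 equaled the count divided by a fixed gene length and the library total within 0.1%. FPKM were thus a rescaling of the counts and no second measurement.

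The tables listed 24031 genes, 16792 protein-coding and 7239 non-coding, and no gene was at 0 in all libraries. Library totals were 36224205 to 39019044 counts. A gene with 0 counts could have had up to 3 counts by chance, which is 0.0769 to 0.0828 CPM (counts scaled to the library total). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

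Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, within each cell line. Genes with at least 10 counts in at least 1 library of the cell line were kept. Log2 fold changes of each library against its control came from TMM-scaled log2 CPM with a prior count of 2. KYSE520 knockdown was tested against shControl with edgeR (glmQLFit and glmQLFTest, two-sided) at a Benjamini-Hochberg adjusted p (FDR) of 0.05. The SE given with its estimates is the absolute log2 fold change divided by the square root of the F statistic, since edgeR reports none. The spread in this test had 1 residual degree of freedom, from the 2 knockdown libraries, and the lone control was assumed to vary like them. edgeR drew each gene's spread towards that of all genes, with 46.0 prior degrees of freedom against 1 residual. The p-values of this test thus rest mostly on a spread pooled over genes. They measure only the spread between these libraries, which may be technical. KYSE30 had 1 library per condition, so its main comparison had no p-value. Genes with an absolute log2 fold change of at least 1 (a fold of 2) were counted by size instead, and ratios of counts were given exact conditional binomial (Clopper-Pearson) 95% intervals. The number expected from counting error alone was simulated with Poisson counts in 20 draws. As an alternative, edgeR tested KYSE30 with the spread borrowed from the KYSE520 knockdown libraries, which is no replicate error of KYSE30.

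A total of 31 gene lists were fixed before the data were examined. They covered the GPRC5 receptor family, EMT and mesenchymal genes, epithelial junction genes, squamous differentiation genes, basal squamous genes, matrix proteases and inhibitors, integrins and focal adhesion, proliferation, interferon response, NF-kB and inflammatory cytokines, STAT3 targets, retinoic acid response, ERK pathway output, EGF receptor ligands and receptors, YAP targets, TGF-beta targets, Wnt targets, p53 targets, hypoxia and glycolysis, unfolded protein and amino acid stress, NRF2 targets, cholesterol synthesis, antigen presentation, trophoblast genes, replication-dependent histones, mitochondrially encoded genes, cytosolic ribosomal proteins, and markers of fibroblasts, leukocytes, endothelium and glandular epithelium. The lists of mitochondrially encoded, cytosolic ribosomal protein and replication-dependent histone genes were fixed as measures of RNA and library quality. Some genes, such as MYC, stood in more than 1 list. Lists with at least 5 measured members were summarised by their median log2 fold change and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. In KYSE520, lists were also tested with camera in limma, with a preset correlation of 0.01 and again with the correlation estimated from the data. Random lists hold unrelated genes, so a percentile describes the libraries and is not a test between conditions.

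Named genes followed a rule written before the data were examined. It took GPRC5A, the 12 highest and 12 lowest genes with a mean CPM of at least 5 in each cell line, 6 genes of each opposite-direction class, and up to 4 members of each list with a mean CPM of at least 1. In KYSE520 genes were ranked by the smaller of their 2 fold changes, and since none met the FDR and size conditions together, the ranking was filled without them. Alternatives included DESeq2 size factors (RLE), library size only, other count minimums, other prior counts, other size thresholds, DESeq2 1.42.0, an edgeR likelihood ratio test, limma on log2(FPKM + 1), all 5 libraries in one fit, and each knockdown library alone. A minimum mean CPM of 5 for the counts by size was added after seeing the data.

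The steps were tested on simulated data with known changes. At FDR 0.05 the KYSE520 test called 4.69%, 50.0% and 77.4% of genes changed by 1, 2 and 3 on the log2 scale, with 4 of 15942 unchanged genes called. The count by size in both knockdown libraries recovered 34.4%, 90.6% and 95.2%, with 4.25% of unchanged genes counted. In simulated KYSE30 libraries the count by size recovered 46.0%, 89.4% and 100% of changed genes and also counted 10.4% of unchanged genes. Their spread, like that of the simulated KYSE520 libraries, was taken from the KYSE520 knockdown libraries, since KYSE30 had no replicates. That spread includes any difference between the 2 knockdowns. Each changed gene was given the same change in both simulated knockdown libraries. The KYSE520 shares therefore need not hold for genes that respond unequally.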

Results

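The study changed the level of GPRC5A, a retinoic acid-inducible orphan G protein-coupled receptor, in KYSE30 and KYSE520, both cell lines of esophageal squamous cell carcinoma. Its title relates this gene to trophoblast and asks about migration and invasion. Gene counts were available for 5 libraries without replication in 3 of the 4 groups. The KYSE30 control library held 39019044 counts and the KYSE30 overexpression library 38264129. In KYSE520 the shControl library held 36947899 counts, knockdown library 1 held 38308792 and knockdown library 2 held 36224205. Between 19031 and 20343 genes had at least 1 count per library.

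GPRC5A (Entrez 9052) was higher in the overexpression library and lower in both knockdown libraries. In KYSE30 it had 48997 counts in the control and 206273 with overexpression, a log2 fold change of 2.18 (95% interval of the ratio 2.16 to 2.19). In KYSE520 it had 11727 counts with shControl, 8917 in knockdown library 1 and 2913 in knockdown library 2, with log2 fold changes of -0.49 and -2.08. The level was thus 26.7% below the control in CPM in knockdown library 1 and 74.7% below it in knockdown library 2. The control level itself was 1256 CPM in KYSE30 and 317.4 CPM in KYSE520. The edgeR estimate for knockdown was -1.08 (SE 0.36), lower in 2 of 2 knockdown libraries, and did not pass over all genes (FDR = 1.00). Adjusted over the list alone, the 3 measured GPRC5 family members, the edgeR p for GPRC5A was 0.0133. Of its relatives, GPRC5B was at 1.13 and GPRC5C at 1.17 with overexpression, while in knockdown libraries 1 and 2 GPRC5B was at 0.11 and -1.38 and GPRC5C at 0.65 and 0.85.

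**Figure D1:**
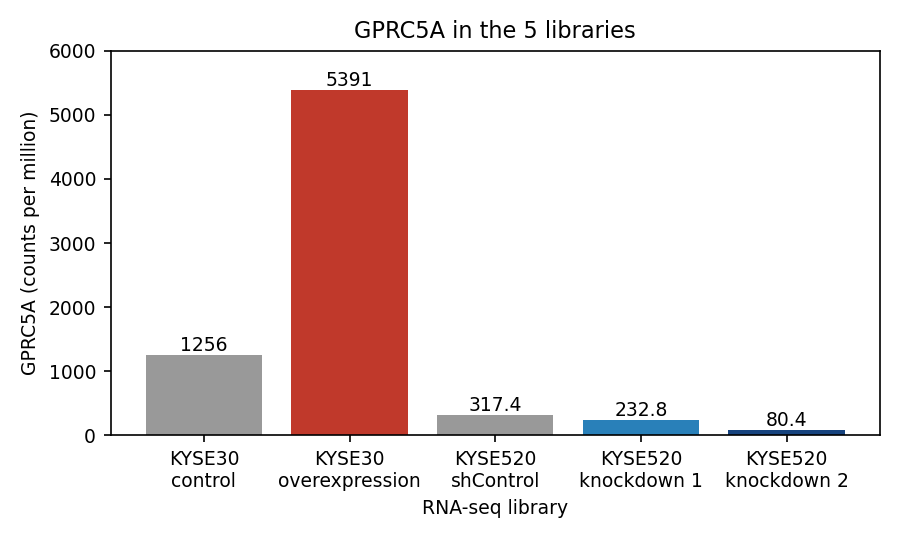
Bars show GPRC5A in CPM (vertical axis, from 0) in each of the 5 RNA-seq libraries (horizontal axis), 1 bar per library and no error bars since each bar is a single library. The overexpression library stood at 5391 CPM against 1256 CPM in its control, and the knockdown libraries at 232.8 and 80.4 CPM against 317.4 CPM.

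The KYSE30 comparison asked what differs in the transcriptome when GPRC5A is raised. Genes of DNA replication and mitosis were lower with overexpression. All 30 measured proliferation genes were at least 2-fold lower, with a median log2 fold change of -1.92. STAT3 targets, trophoblast genes, antigen presentation genes, YAP targets and NF-kB genes were higher, with medians of 1.29, 1.11, 0.97, 0.84 and 0.82. Among the single genes with the highest fold changes were LCN2, which encodes the iron-binding protein lipocalin 2, the pregnancy-specific glycoprotein gene PSG1 and the complement gene C3. Of 15777 genes, 1842 were higher and 1715 lower by at least 1 on the log2 scale, where counting error alone gave 141 in simulations. With the spread of the KYSE520 knockdown libraries, 1570 of 15102 simulated unchanged genes passed this size.

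Proliferation genes moved as a block in KYSE30. MKI67, the gene of the Ki-67 antigen, went from 38005 to 5818 counts, a log2 fold change of -2.61 (95% interval -2.65 to -2.57). RRM2, a subunit of ribonucleotide reductase, was at -2.34, the mitotic kinesin KIF11 at -2.25 and cyclin B1 (CCNB1) at -2.23. Outside the list, the 12 genes with the lowest fold changes included the kinetochore gene ZWINT (-3.11), the replicative helicase subunit gene GINS4 (-2.91), the cohesion gene ESCO2 (-2.81), GTSE1 (-2.80), the replication checkpoint gene CLSPN (-2.78) and the cell cycle regulator E2F7 (-2.70). The p53 target list had a median of -0.04, within the range of random lists, and replication-dependent histone genes had a median of -0.26, also within it.

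Targets of cytokine signaling were higher with overexpression. Of 20 STAT3 targets, 12 were at least 2-fold higher and none as much lower, with LRG1 at 3.51, CEBPD at 2.71, MYC at 1.98 and the feedback inhibitor SOCS3 at 1.94 (95% interval 1.84 to 2.04). Of 22 NF-kB and inflammatory cytokine genes, 8 were at least 2-fold higher and 1 lower, among them the NF-kB subunit RELB at 2.25, NFKB2 at 1.82 and BIRC3 at 2.17. Of 20 antigen presentation genes, 10 were higher and 1 lower by size, with HLA-F at 2.09, the peptide transporter TAP1 at 1.79 and HLA-E at 1.60. Without the HLA genes, whose reads can be shared, the 13 remaining members had a median of 0.73. Interferon response genes were split, with 7 higher and 4 lower by size and a median of 0.25. In that list IFI44L was at 3.96 and BST2 at 3.68, while IFIT1 was at -2.03.

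Genes of adhesion, matrix and cell shape differed by member in KYSE30. Of 24 YAP targets, 11 were at least 2-fold higher and none lower, with ANKRD1 at 2.99, F3 (tissue factor) at 2.18, AMOTL2 at 2.12 and CCN1 at 2.08 (95% interval 2.06 to 2.11). Matrix proteases and inhibitors had a median of 0.54, with the urokinase gene PLAU at 1.57 and TIMP2 at 1.34, but the inhibitor TIMP3 at -3.01. EMT and mesenchymal genes had a median of 0.57, with 8 higher and 2 lower by size. Members of that list went both ways, with the EMT transcription factor SNAI1 at 1.92 and the related SNAI2 at -1.30, TAGLN at 1.71 and the matrix gene TNC at -2.47. E-cadherin (CDH1) was at 0.08 with 19766 and 19514 counts. TGF-beta targets had a median of 0.39, with TGFB2 at 1.82, INHBA at 1.67 and PMEPA1 at 1.26. Wnt targets had a median of 0.58, with 4 higher and 5 lower by size, including WNT7B at 1.84 and DKK1 at -1.15. Integrins and focal adhesion genes had a median of 0.22, within the range of random lists, although ITGB6 was at 1.86 and ITGB4 at 1.47.

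Trophoblast genes were among the lists with the highest medians in KYSE30. Of 32 measured members, 17 were at least 2-fold higher and 5 lower. PSG1 went from 28 to 948 counts, a log2 fold change of 5.08 (95% interval 4.64 to 5.78), and PSG5 from 57 to 973 counts (4.15). PSG genes are close paralogs, so their split among family members is uncertain, and the 27 other members had a median of 0.80. Squamous differentiation genes had a median of 0.17, within the range of random lists, with LCN2 at 5.73 (40 and 2080 counts) and KRT16 at 2.42. Basal squamous genes had a median of 0.24, also within it, with the transcription factors SOX2 at -3.06 and TP63 at -1.58 and the integrin gene ITGB4 at 1.47. Epithelial junction genes had a median of 0.16, within the range, with claudin 1 (CLDN1) at 2.29 (6956 and 31683 counts).

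Metabolic and stress lists had smaller medians, in absolute size, than the proliferation, STAT3 and trophoblast lists in KYSE30. Cholesterol synthesis genes had a median of 0.29, with MSMO1 at 1.55 and the desaturase gene SCD at 1.23. NRF2 targets had a median of 0.32 and retinoic acid response genes a median of 0.40, with transglutaminase 2 (TGM2) at 4.20. Mitochondrially encoded genes had a median of -0.50 and were lower in 13 of 13 members, and their share of counts was 5.62% in the control and 3.99% with overexpression. Medians within the range of random lists were found for ERK pathway output (0.24), EGF receptor ligands and receptors (0.18), hypoxia and glycolysis (-0.03), unfolded protein and amino acid stress (0.08) and cytosolic ribosomal proteins (0.12). Among markers of other cell types, leukocyte markers had a median of 0.69 and glandular epithelial markers of -0.22, both within the range, with CD68 at 2.06. Only 2 fibroblast and 3 endothelial markers were measured, with medians of 0.66 and -0.92, too few for a percentile.

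Genes with the highest single fold changes in KYSE30 included the GABA receptor subunit gene GABRP (27 and 1717 counts, 5.99, 95% interval 5.55 to 6.70), the ubiquitin ligase gene NEURL3 (5.06), SHC2 (4.66), ADAMTSL4 (4.64), C3 (138 and 3141 counts, 4.59), the interferon-induced IFITM1 (4.53) and the potassium channel gene KCNK5 (4.35). In the opposite direction stood LFNG (-3.13), a modifier of Notch receptors, and GDAP1 (-2.68). With 1 library per condition there was no replicate error to set these differences against. Among genes with a mean CPM of at least 5 the count by size was 699 higher and 695 lower of 10747, and 369 genes passed FDR 0.05 when edgeR borrowed the spread of the KYSE520 knockdown libraries.

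**Figure D2:**
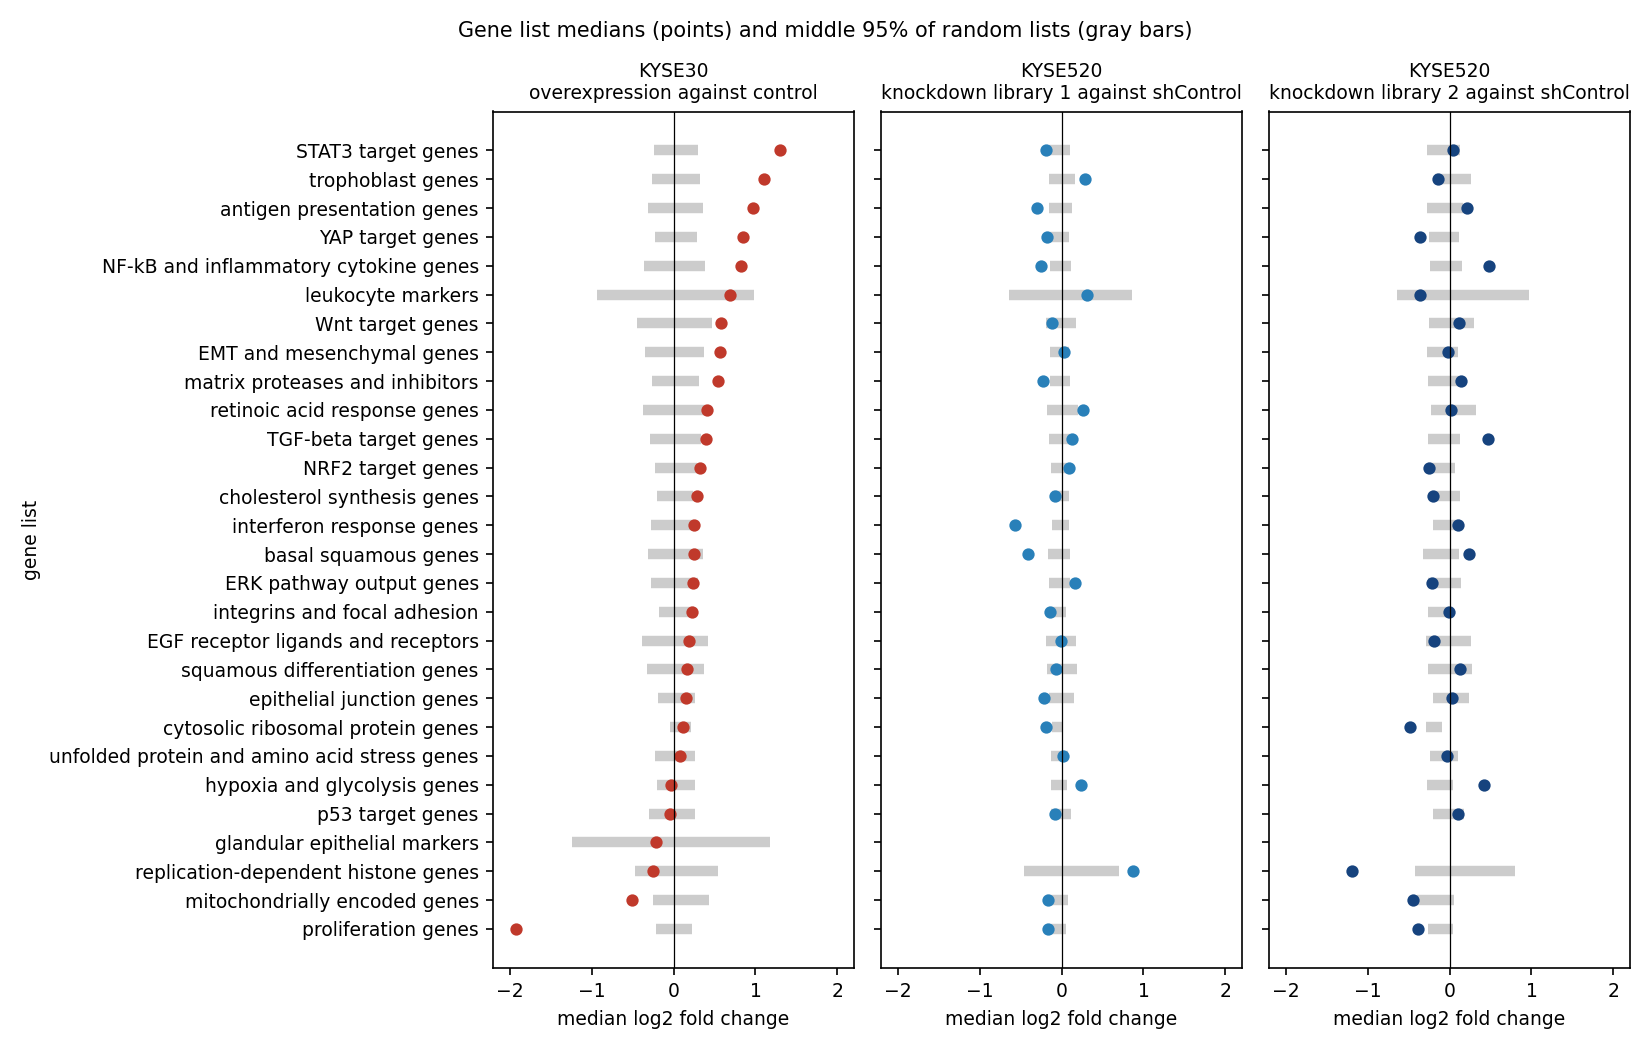
Points show the median log2 fold change (horizontal axis) of each gene list (vertical axis) in 3 panels, the KYSE30 overexpression library against its control and each KYSE520 knockdown library against shControl, and gray bars show the middle 95% of medians of random lists matched on expression. In KYSE30 the proliferation list lies at -1.92 and STAT3 targets at 1.29, while in KYSE520 lists such as replication-dependent histones lie on opposite sides in the 2 knockdown libraries (0.87 and -1.19).

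**Figure D3:**
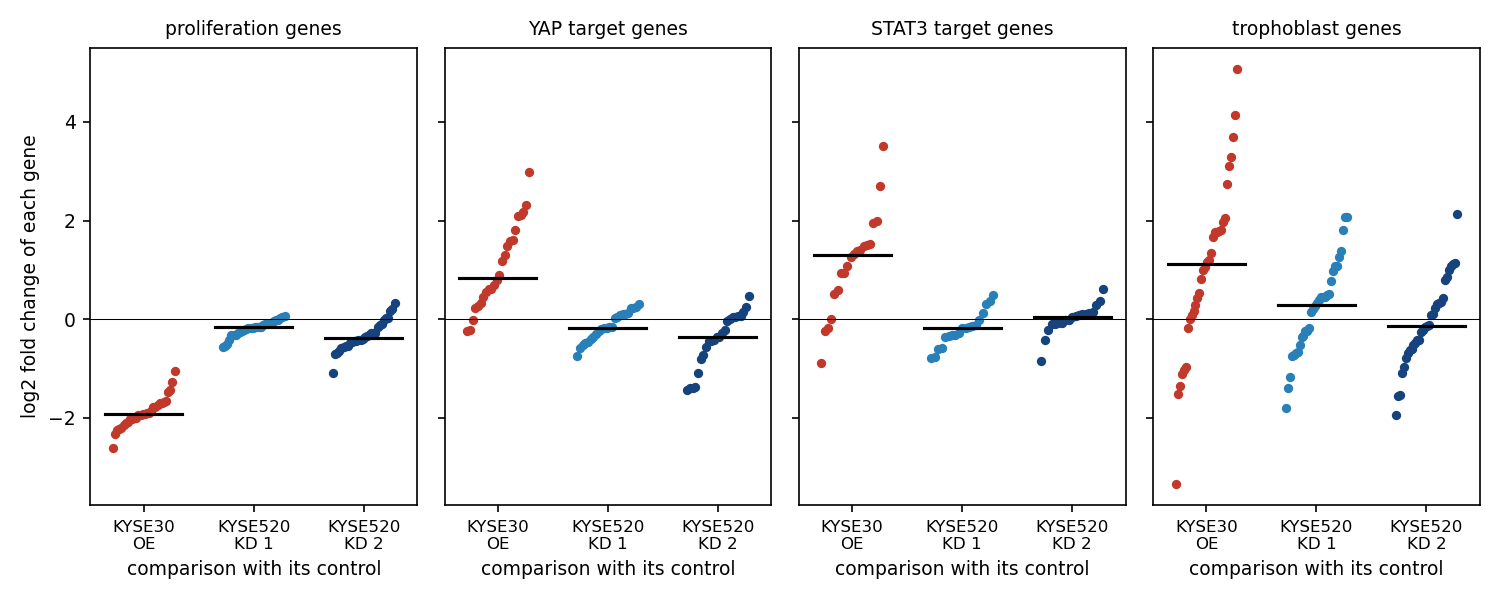
Each point is the log2 fold change (vertical axis) of 1 measured gene of 4 lists, in the KYSE30 overexpression library (OE) and in KYSE520 knockdown libraries 1 and 2 (KD), each against its control, sorted from low to high, and black lines are medians. All 30 proliferation genes lie below -1 in KYSE30, and 1 trophoblast gene at 0 counts with overexpression is drawn at its fitted value, which leaves the list's median at 1.11 when set to the floor of 3 counts.

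The KYSE520 comparison asked what differs when GPRC5A is lowered. ZBED2 and CYP24A1 rose with knockdown, both mainly in knockdown library 2. Hypoxia and glycolysis genes were higher in both knockdown libraries, with medians of 0.23 and 0.42. Proliferation genes, YAP targets and cytosolic ribosomal protein genes were lower in both. Both libraries were set against the same shControl library, so a trait of that library alone could move these lists alike. Several lists, among them NF-kB genes, antigen presentation genes and histones, lay on opposite sides in the 2 knockdown libraries.

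ZBED2 (Entrez 79413), a BED-type zinc finger gene, had 121 counts with shControl and 257 and 2131 counts in knockdown libraries 1 and 2. Its edgeR log2 fold change was 3.23 (SE 0.60, FDR = 0.0311), higher in 2 of 2 knockdown libraries, with 0.98 and 4.04 in the single libraries. CYP24A1 (Entrez 1591), the vitamin D 24-hydroxylase gene, had 223, 363 and 3859 counts, and its edgeR log2 fold change was 3.17 (SE 0.60, FDR = 0.0311), with 0.61 and 4.03 in the single libraries. Each of these 2 genes differed widely between the knockdown libraries, so the calls do not reflect agreement between those libraries. Both genes were singled out after their values were seen. They were the only genes of 16681 to pass in edgeR, where 366 genes (2.19%) had an unadjusted p under 0.05. The call depends on the settings, since DESeq2 called 0 genes with 168 at an unadjusted p under 0.05, limma on log2(FPKM + 1) called 0 with 291, an edgeR fit of all 5 libraries called 0 with 306, and an edgeR likelihood ratio test called 3 with 472. Over 8 alternatives the adjusted p of each of the pair ranged from 0.00066 to 1.00, and each passed in 2.

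Among 28 lists tested with camera, 7 passed at an adjusted p of 0.05 with the preset correlation. None of the 7 passed when the correlation was estimated from the 1 residual degree of freedom (camera, adjusted p = 0.945 for each), so each call rests on the preset correlation. With 1 degree of freedom that setting could hardly call any list, so its result does not show that list members were correlated. For retinoic acid response genes the estimate was -0.0588, below the preset 0.01, and the call ended too. Hypoxia and glycolysis genes rose (adjusted p = 1.43e-08, or adjusted p = 0.945 with an estimated correlation), with medians of 0.23 and 0.42 in the 2 libraries and 24 of 30 members above 0 in the mean. In this list EGLN3, an oxygen-sensing prolyl hydroxylase gene, was at 0.21 and 2.76, P4HA1 at 0.88 and 1.11, ENO2 at 0.64 and 1.01 and BNIP3 at 0.57 and 1.02. TGF-beta targets rose (adjusted p = 0.000942, or adjusted p = 0.945 with an estimated correlation), with medians of 0.13 and 0.47, PMEPA1 at 0.84 and 1.57 and TGFBI at 0.29 and 1.54. Retinoic acid response genes were called higher (camera, adjusted p = 0.0104, or adjusted p = 0.945 with an estimated correlation). Their medians were 0.26 and 0.02, with the retinol transporter gene STRA6 at 1.47 and 2.68. In knockdown library 2 this median lay within the range of random lists, at percentile 50.2. Proliferation genes fell (adjusted p = 2.58e-06, or adjusted p = 0.945 with an estimated correlation), with medians of -0.17 and -0.38 and 26 of 30 members below 0 in the mean. YAP targets fell (camera, adjusted p = 0.000155, or adjusted p = 0.945 with an estimated correlation). Their medians were -0.17 and -0.36, and CCN1 was at -0.25 and -1.40. Of the 24 YAP targets, 10 were above 0 in knockdown library 1 and 7 in knockdown library 2. Cytosolic ribosomal protein genes fell (adjusted p = 2.65e-16, or adjusted p = 0.945 with an estimated correlation), with medians of -0.19 and -0.48 and 74 of 74 members below 0 in the mean. Mitochondrially encoded genes fell (adjusted p = 0.00253, or adjusted p = 0.945 with an estimated correlation), with medians of -0.16 and -0.45, and their share of counts was 4.12% with shControl and 3.75% and 3.09% with knockdown. The ribosomal protein and mitochondrially encoded lists were fixed as measures of RNA and library quality. A difference in quality was not separated from an effect of knockdown. Without a low-count filter the calls of TGF-beta targets (camera, adjusted p = 0.150) and retinoic acid response genes (adjusted p = 0.644) ended.

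The other 21 lists did not pass in camera, and no list held more than 1 gene past the edgeR test when adjusted over the list alone. Besides GPRC5A those genes were CLDN1, KRT5, STRA6, EREG, EGLN3 and the fibroblast collagen gene COL3A1, from STRA6 (edgeR, adjusted p = 0.00273 over the list alone) to EREG (adjusted p = 0.0430). Over all genes tested none of these passed, the lowest FDR being 0.383 for STRA6. Median, mean and camera direction differed in sign for squamous differentiation, ERK output, EGF receptor, antigen presentation, trophoblast and leukocyte lists. Trophoblast genes had medians of 0.29 and -0.15 in knockdown libraries 1 and 2. EMT and mesenchymal genes had medians of 0.03 and -0.02, the latter turning to 0.09 when only library size was scaled, which shifted the median of all genes in knockdown library 2 by 0.101.

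Knockdown libraries 1 and 2 differed from each other more than either did from shControl. By size, 1518 genes separated knockdown library 1 from shControl, 1913 separated knockdown library 2 from it, and 2317 separated the knockdown libraries. Basal squamous genes had medians of -0.41 and 0.24, matrix proteases and inhibitors of -0.22 and 0.14, NF-kB genes of -0.25 and 0.49, antigen presentation genes of -0.30 and 0.21 and histones of 0.87 and -1.19. Interferon response genes were at -0.57 in library 1 and 0.11 in library 2, with RSAD2 at -1.25 and -0.08. The prostaglandin synthase gene PTGS2 was at -0.07 and 1.42, and the histone gene H1-2 at 0.87 and -1.56.

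Genes that went the same way in both knockdown libraries without passing the test included a retinol transporter, collagen and growth factor genes. STRA6 had 68, 205 and 470 counts, BMP2 had 916, 2016 and 3209 (1.04 and 1.73), the EGF receptor ligand EREG had 227, 548 and 630 (1.17 and 1.39), SAMD11 was at 1.39 and 1.67 and the non-coding WAKMAR2 at 1.95 and 1.57. COL3A1 had 623, 217 and 271 counts (-1.61 and -1.27), the activin antagonist follistatin (FST) had 10005, 5163 and 4736 (-1.05 and -1.15), KRT5 was at -1.22 and -0.98 and FGFBP1 at -0.80 and -1.92. By size 364 genes were higher and 168 lower in both libraries. With no low-count filter these were 527 and 623. Both libraries share 1 control, which alone makes genes overlap. Simulated unchanged libraries gave 441 and 317 with the spread between the knockdown libraries, which includes any difference between the knockdowns, and 34.6 and 12.9 with counting error only, so the overlap does not settle whether there was a shared response. With a mean CPM of at least 5 the counts were 14 and 2.

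**Figure D4:**
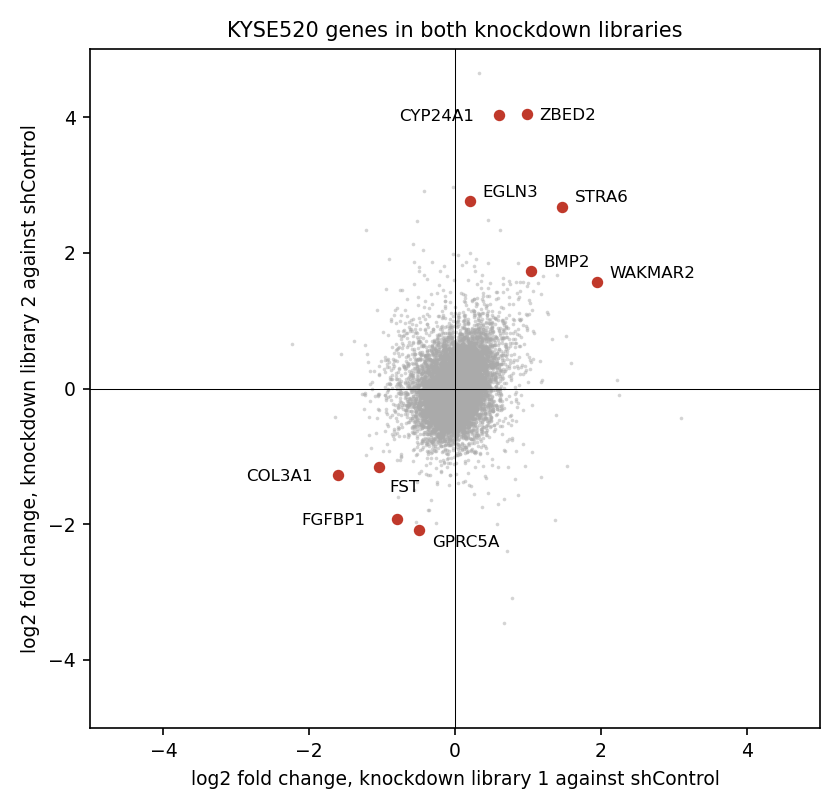
Each gray point is 1 of 11027 genes with a mean CPM of at least 5 in KYSE520, with its log2 fold change against the same shControl library in knockdown library 1 (horizontal axis) and knockdown library 2 (vertical axis), and red points are named genes. ZBED2 (0.98 and 4.04) and CYP24A1 (0.61 and 4.03) lie high on the vertical axis, and GPRC5A lies at -0.49 and -2.08.

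The comparison between the cell lines asked which genes followed GPRC5A in both. CLDN1, a tight junction gene, was at 2.29 with overexpression and at -1.16 and -0.87 in the 2 knockdown libraries. FGFBP1, which encodes a carrier of fibroblast growth factors, was at 1.46, -0.80 and -1.92, the matrix gene THBS1 at 1.05, -0.91 and -0.92, and TSPAN2 at 3.32, -0.96 and -0.62. In the reverse direction, EREG was at -0.79, 1.17 and 1.39, ZNF107 at -1.23, 0.89 and 1.02 and the glycolytic regulator gene PFKFB4 at -1.21, 0.71 and 0.76. The YAP list was the 1 list of 27 with a median above the range of random lists with overexpression (0.84) and below it in both knockdown libraries (-0.17 and -0.36). In KYSE30, 15 lists lay outside that range. How many lists would meet all these conditions without a link between the cell lines was not computed. Both knockdown medians share the same shControl library, so they are not independent of each other.

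By size and by correlation across all genes, the cell lines showed little common change. Of 14533 genes measured in both, 16 were higher with overexpression and lower in both knockdown libraries by size, where matching genes at random within expression bins gave 19.6, and 32 went the reverse way, where it gave 41.8. With library size only these were 11 and 43. GPRC5A itself, at -0.49 in knockdown library 1, did not reach the size threshold there. These counts can therefore miss genes that follow it. Genes going the same way in both lines numbered 39 higher, where chance gave 44.6, and 14 lower, where it gave 18.9. The correlation of fold changes across genes, which are not independent replicates, was 0.0287 between overexpression and mean knockdown. No gene with a mean CPM of at least 5 in each line passed the size threshold in opposite directions in all 3 libraries, so the genes named here are those nearest to it. Over all 14533 genes, knockdown library 2 alone gave 104 genes higher with overexpression and lower with knockdown and 113 of the reverse, where chance within expression bins gave 86.9 and 124, and knockdown library 1 alone gave 79 and 93, where it gave 73.3 and 96.7.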

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

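The tests of GC content and gene length were chosen before their results were seen, and all other tests in this part after. The following 4 results moved in the same direction in both cell lines, although GPRC5A was raised in one and lowered in the other. In none of them was the difference between the cell lines tested. Both knockdown values of each result share the same shControl library.

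The median of the proliferation genes was -1.92 with overexpression in KYSE30 and -0.17 and -0.38 in the KYSE520 knockdown libraries, lower than random lists in all 3. A trend with gene length or GC content is argued against, since removing it left the KYSE30 median at -1.84. A denser culture with contact inhibition was not settled. YAP targets, which fall in dense cultures, had a median of 0.84 in the same library. That value was known when the test was chosen, and something else may have raised these targets. Another difference between the 2 KYSE30 cultures stays open and cannot be told apart from an effect of GPRC5A in this line, because each condition had 1 library.

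TGF-beta targets had a median of 0.39 with overexpression and of 0.13 and 0.47 in the knockdown libraries. SEPTIN3, a septin gene, was at 1.88 with overexpression and at 1.14 and 1.56 with knockdown. RCOR2, a corepressor gene, was at 1.14 with overexpression and at 1.06 and 1.16 with knockdown.

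YAP targets had a median of 0.84 with overexpression and of -0.17 and -0.36 in the knockdown libraries, and may follow GPRC5A in both cell lines, a hypothesis found and tested on the same data. A trend with gene length or GC content is argued against, since removing it left medians of 0.74, -0.14 and -0.30. Recent serum stimulation or handling stays open, because 9 immediate-early genes had a median of 0.81 with overexpression but of -0.22 and 0.46 with knockdown, and single members went both ways. Another difference between cultures also stays open, with 1 library per KYSE30 condition and 1 shControl library behind both knockdown medians. Camera did not call this list with a correlation estimated from the data. There 0 lists passed, and with 1 residual degree of freedom hardly any could, so that result cannot decide about this list.

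In KYSE520, 5 of 28 lists lay above the middle 95% of random lists in one knockdown library and below it in the other, namely basal squamous, matrix protease, NF-kB, antigen presentation and histone genes, where independent libraries and unrelated genes would give 0.035. Co-regulated genes widen that range of chance. Many other lists also lay outside the middle 95% in a single knockdown library, so 0.035 is too low a yardstick. The histone list was fixed as a measure of RNA and library quality. A trend with gene length or GC content explained 6.60% of the variance of fold changes in knockdown library 2 and 0.681% in library 1. It is argued against as the whole cause, since after its removal 7 lists lay at opposite ends, including all 5. Differences between hairpins or between single cultures cannot be told apart, because each numbered knockdown had 1 culture, and no biological explanation was tested.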

How the results depend on the processing

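The minimum mean CPM of 5 was chosen after seeing the data and the other alternatives before. No paired analysis was possible because no label links a library of one group to a library of another. Without a knockdown library the KYSE520 test had no residual degrees of freedom, so no count past FDR 0.05 was made there. Depth limited genes with few counts, and counting error alone put 141 KYSE30 genes past the size threshold where 3557 were seen. The spread of the KYSE520 knockdown libraries put 1570 of 15102 simulated unchanged genes past it. The 2 genes past FDR 0.05 became 0 with library size only, with no low-count filter, with at least 50 counts, with the DESeq2 Wald test, with all 5 libraries in one fit and with limma on log2(FPKM + 1), and 3 with RLE and the likelihood ratio test. The 532 genes past the size threshold in both knockdown libraries became 1150 with no filter, 87 with at least 50 counts, 144 with a prior count of 10, 4 with log2(FPKM + 1), 1276 and 83 at thresholds of 0.6 and 2, 16 with a mean CPM of at least 5, and 1518 to 1913 with 1 knockdown library left out. The 3557 genes in KYSE30 became 2277 with at least 50 counts, 1082 with log2(FPKM + 1), 6492 and 965 at thresholds of 0.6 and 2, 1394 with a mean CPM of at least 5, and 369 with the spread borrowed from KYSE520. The 48 genes in opposite directions between the cell lines became 156 with no filter, 6 with at least 50 counts, 73 and 8 with prior counts of 0.5 and 10, 0 with log2(FPKM + 1), 216 and 3 at thresholds of 0.6 and 2, 0 with a mean CPM of at least 5, and 172 to 217 with 1 knockdown library left out. Stricter filters, larger prior counts and higher thresholds leave fewer genes by construction, and the cause of the other changes was not tested. The 7 lists called by camera became 0 with a correlation estimated from the data, where 1 residual degree of freedom could hardly call any list. With no low-count filter they became 5. With at least 50 counts they became 9, the added lists being basal squamous genes and fibroblast markers, both lower. Of 11 KYSE520 list medians outside the range of random lists or called by camera, 3 changed sign under an alternative or in a single knockdown library. Of the other 17, 15 did, 14 of them in a single knockdown library. In KYSE30 none of 15 medians outside the range changed sign and 5 of the other 13 did. That of squamous differentiation genes was 0.21, -0.0026 with at least 50 counts and -0.073 to 0.13 in the single libraries. That of EMT and mesenchymal genes was 0.16, and -0.017 to 0.033 in the single libraries. That of interferon response genes was -0.19, and -0.57 to 0.11 in the single libraries. Outside the left-out libraries, 269 values of list medians stayed within the spread between the knockdown libraries (in KYSE30, the spread of random lists) and 10 moved by more, and 2479 values of named genes stayed within the spread between the knockdown libraries (in KYSE30, their counting interval) while 295 moved. The KYSE30 count of 15 lists outside the range of random lists was 13 to 15 under RLE, library size only and both other filters.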

Other observations

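Pathways of the annotation in the deposited tables, 303 in number, were examined after the lists and without a fixed choice. In KYSE30, 100 of them had a median outside the middle 95% of random lists, where 5% is expected of unrelated genes. DNA replication genes had a median log2 fold change of -1.23 with overexpression, with 25 of 35 at least 2-fold lower. Mismatch repair genes had a median of -1.08 (12 of 22), homologous recombination genes of -0.92 (17 of 39) and Fanconi anemia genes of -0.89 (24 of 51). Proteasome genes had a median of -0.54, spliceosome genes of -0.36 and oxidative phosphorylation genes of -0.34. Genes of the complement and coagulation cascades had a median of 0.95, with 19 of 40 at least 2-fold higher. ECM-receptor interaction genes had a median of 0.64 (21 of 60) and cytokine-cytokine receptor interaction genes of 0.46 (36 of 134). These directions were the same with RLE and with library size only.

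In KYSE520, 44 pathways in knockdown library 1 and 56 in knockdown library 2 lay outside the range. In knockdown library 2, with the lower GPRC5A level, the 74 ribosome biogenesis genes had a median of -0.42 and RNA polymerase genes of -0.35. The same pathways were at -0.01 and -0.07 in knockdown library 1, the former at 0.03 with library size only. TNF signaling genes were at 0.15 in knockdown library 2 and at -0.06 in knockdown library 1.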
